A study of Mus musculus with 18 samples.

How the data were processed

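Gene expression was measured by RNA sequencing in a mouse embryonic stem (ES) cell line that carries a tdTomato reporter at Msx1, kept with serum and LIF, and in lines derived for doxycycline-inducible expression of Dlx2 or GFP. Embryoid bodies (EBs) were formed in hanging drops with 1 µg/ml doxycycline, and cells of the later stages were sorted by flow cytometry into Msx1-positive and Msx1-negative fractions at days 8 and 16. Total RNA was extracted with TRI Reagent, and libraries were made with a NEBNext Ultra RNA kit, which does not mark the strand of the transcript. Reads of genes that overlap on opposite strands are therefore not separated by strand.

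The authors deposited 2 tables of raw read counts per gene symbol, with a column per library. Both hold whole numbers and were treated as counts without normalisation. The submitters' processing notes name fastp 0.20.0, HISAT2 2.1.0, DESeq2 1.18.1 and the mouse genome build GRCm38. The counting program and the gene annotation are not given in the sources used here. The day-2 table lists 26157 symbols and holds only symbols with a summed count of at least 5 over its libraries. The table of days 8 and 16 lists 54114 symbols, of which 17435 have no count in any library. At day 2, 26 symbols had been turned into dates, and they were kept as they stand. Coordinates were taken by symbol from GENCODE vM21, on GRCm38, which matched 25603 symbols of the day-2 table and 53263 of the other.

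The labels describe 18 samples in 9 groups of 2. Of these, 14 libraries in 7 groups have a column: induced Dlx2 and induced GFP EBs at day 2, ES cells, and Msx1-positive and Msx1-negative cells at days 8 and 16. The day-2 columns name the Dlx2 and GFP lines without naming doxycycline, and were read as the induced groups because the study design compares overexpressing EBs of both lines. The 4 samples of the 2 uninduced groups were not analysed here. Total counts ran from 26211608 to 41552818 per day-2 library and from 53797597 to 107770730 per library of the other table. Counting limits are given as follows. Where every library of a group had a count of 0, the fold is a lower bound computed against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its 95% exact counting interval. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

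Comparisons, tests and gene lists were fixed before the data were examined. Each table was fitted on its own, the day-2 table with its 4 libraries and the other table with the 8 sorted libraries. Genes were kept by edgeR's filterByExpr with the groups, which left 18650 genes at day 2 and 22294 at days 8 and 16. Counts were scaled by TMM and tested by edgeR's quasi-likelihood method (glmQLFit with robust estimation, then glmQLFTest, both sides). P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. The fixed comparisons that were run are induced Dlx2 against induced GFP EBs, Msx1-positive against Msx1-negative cells at day 8 and at day 16, the difference between those effects, and day 16 against day 8 within each sorted fraction. Of the 12 fixed comparisons, 6 were not run. Those that need the uninduced groups lacked their columns here, and EBs were not tested against ES cells because these stand in separate tables. The day-2 fit accordingly held 4 libraries in place of the 10 foreseen. Comparisons of the 4 sorted groups with ES cells were added after the layout of the tables had been seen, in a fit of 10 libraries and 22504 genes. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Levels are CPM, counts scaled to library size with TMM factors, as mean ± SD of n = 2 libraries. Changes are log2 fold changes with a standard error (SE). It was back-computed as the absolute log2 change divided by the square root of the quasi-likelihood F. This SE can be too small where a group has few counts.

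Gene groups were tested with camera, which asks whether the members of a list moved more than the other genes. It was run on log2 CPM with a prior count of 3 and a preset correlation between genes of 0.01, for lists with at least 5 tested members, and adjusted over the lists of a comparison. The 35 lists were: naive pluripotency, formative and primed pluripotency, core pluripotency, 2-cell-like, neural crest and plate border specifiers, ectomesenchyme, odontogenic mesenchyme, primitive streak and mesoderm, definitive and primitive endoderm, neural, surface ectoderm and epidermis, trophectoderm, cardiac muscle, endothelium, blood, smooth muscle and pericyte, skeletal muscle, osteoblast, chondrocyte, glia and melanocyte, peripheral neuron, mesenchymal matrix and EMT, epithelial adhesion, BMP response, WNT response, FGF and ERK response, retinoic acid response, Hox clusters, nuclear lamina and LAP2 partners, cell cycle, p53 response, immediate early and dissociation stress, hypoxia and glycolysis, mitochondrially encoded, and replication-dependent histones. Some genes stand in more than 1 list. The histone list had under 5 tested members at days 8 and 16 and was tested at day 2 only. Members are counted over all genes tested and adjusted over the list alone. A list's median places genes with 0 counts in every library of a group at their bound.

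The genes named follow a rule fixed with the lists. It takes 11 genes chosen for the question (Dlx2, Msx1, Tmpo, Pou5f1, Nanog, Sox2, Twist1, Prrx1, Pdgfra, Tfap2a and Sox10), of which the text prints those it needs. To these it adds, per comparison, the 8 highest and 8 lowest log2 changes, or 5 and 5 outside the primary comparisons. These had to be called, to reach a mean of 5 CPM in the higher group, to have no overlap between the replicates of both groups, and to carry a symbol that is not of a predicted or clone type. For a difference between effects the overlap condition was dropped. From each list described, up to 4 members with the smallest p-values may be named. Some genes that the rule gives are not reported here.

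The alternatives tried were RLE scaling, DESeq2 in place of edgeR, no filter on low counts, a stricter filter of at least 1 CPM in at least 4 libraries, only the compared groups in the fit, a replicate block, an absolute log2 change of at least 1, a threshold of 0.01, leaving out each library in turn, camera with an estimated correlation, and fry. Scaling by library size alone and ES libraries in the fit of the sorted groups were added after the data had been seen. The steps were tested on simulated data, drawn from the measured means and library sizes and from the spread fitted over genes of like level. Known fold changes were put into some genes and lists.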

Results

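The experiment addressed whether forced expression of Dlx2 moves mouse embryonic stem (ES) cells toward ectomesenchyme, the mesenchyme of neural crest origin that builds much of the face and the teeth. Dlx2 encodes a homeobox transcription factor of the pharyngeal arches and the forebrain. The cells carried a tdTomato reporter at Msx1, another homeobox gene of craniofacial mesenchyme, and were grown as embryoid bodies (EBs). RNA was sequenced from 14 libraries in 7 groups of 2: EBs with induced Dlx2 and with induced GFP at day 2, ES cells, and Msx1-positive and Msx1-negative cells sorted at days 8 and 16. The labels give 1 µg/ml doxycycline for all sorted cells, and hold no GFP or uninduced group at days 8 and 16. Total counts were 41552818 and 32579122 for the Dlx2 libraries, 26289399 and 26211608 for GFP, and 54884142 and 53797597 for ES cells. At day 8 they were 65655287 and 107770730 for Msx1-positive and 63489887 and 56048918 for Msx1-negative cells. At day 16 they were 62026265 and 64696124 for Msx1-positive and 59723478 and 60386613 for Msx1-negative cells. Levels are given in CPM, read counts scaled to library size and composition, as mean ± SD of n = 2 libraries. Changes are log2 fold changes ± SE, where the SE was back-computed from the edgeR F statistic. It can be too small for genes with few counts in a group.

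A difference between groups was called at an adjusted p below 0.05, and genes are said to have risen or fallen only where they were called. These p-values measure the spread between libraries alone, and the labels do not state whether replicates came from separate cultures or were technical. With 2 libraries against 2, the smallest two-sided exact p that regrouping a single value can give is 0.333, so every call rests on the spread shared across genes. Scaling by library size alone moved the median of all tested genes to 0.198 at day 2 and 0.217 at day 8, against 0.024 and 0.062 with TMM, and to -0.284 for the difference between the sorting effects, against -0.097. It gave -0.15 for day 16 against day 8 in Msx1-positive cells, against -0.034 with TMM. For gene groups the number of members that rose and fell is given over all genes tested, and the number adjusted over the list alone was the same unless it is printed beside it. The camera test behind the calls of groups used a preset correlation between genes. With an estimated correlation 0 of 14 calls held at day 2, 5 of 17 at day 8 and 8 of 20 at day 16. That form of camera also takes its degrees of freedom from the few libraries of a fit, in place of the many genes. It therefore has less power, least in the small day-2 fit, and a lost call does not show that correlation between genes was the reason. By fry, 31, 27 and 32 lists passed in the same comparisons. In no called list of the 6 fixed comparisons did the median, the mean and the camera direction differ in sign. Fry asks whether the members moved on balance in 1 direction, or in its mixed form in either direction, and does not compare them with other genes.

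The day-2 comparison asked what Dlx2 does early, against EBs that expressed GFP. Of 18650 genes tested, 6367 were higher and 6157 lower with Dlx2, together 67.2% of the genes. Among them 3191 rose and 1798 fell by an absolute log2 change of at least 1. Dlx2 itself (chromosome 2, 71543408 to 71546754 on GRCm38) stood at 4530 ± 270 CPM, against 4 counts in both GFP libraries together, a log2 change of 15.7 (adjusted p = 3.9e-28). The size of this change rests on the 4 GFP counts, so no SE is printed. Dlx2 counts do not separate the introduced from the endogenous gene.

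With Dlx2, Msx1, Prrx1, Pdgfra and Twist1 rose and the pluripotency factors Pou5f1, Nanog and Sox2 fell. Msx1 (chromosome 5, 37820485 to 37824583) reached 15.1 ± 0.78 CPM against 1.32 ± 0.25 with GFP, a log2 change of 3.52 ± 0.17 (adjusted p = 3.43e-14). Prrx1, a homeobox gene of limb and face mesenchyme, rose by 5.39 ± 0.31 to 7.8 ± 0.6 CPM (adjusted p = 7.83e-13). Pdgfra, a growth factor receptor of neural crest mesenchyme and of primitive endoderm, rose by 7.79 ± 0.096 to 234 ± 9.5 CPM (adjusted p = 7.77e-25). Twist1 rose by 1.06 ± 0.14 (adjusted p = 7.93e-07). Of the pluripotency factors, Pou5f1 went from 668 ± 33 CPM with GFP to 166 ± 14 with Dlx2, a change of -2.01 ± 0.057 (adjusted p = 2.02e-18). Nanog changed by -2.08 ± 0.05 (adjusted p = 9e-20) and Sox2 by -1.55 ± 0.049 (adjusted p = 1.16e-17). Tmpo, which encodes the nuclear lamina protein LAP2, was at 250 ± 4.6 against 310 ± 5.2 CPM, a change of -0.31 ± 0.047 (adjusted p = 4.44e-06). Its alpha isoform is not resolved by counts per gene.

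Tfap2a, an early factor of neural crest and epidermis, was at 6.02 ± 0.37 CPM with Dlx2 and 6.42 ± 0.62 with GFP and was not called (adjusted p = 0.622). Sox10, which marks migrating crest and glia, was at 1.47 ± 0.2 against 0.526 ± 0.11 CPM, and its rise of 1.48 ± 0.38 (adjusted p = 0.00156) was no longer called without Dlx2 replicate 1 (1.33, adjusted p = 0.0527).

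Among the highest gains at day 2 were Dlx6os1, Krt25, Nkx2-1, Otp, Fezf2, Tbx5 and Palmd. Dlx6os1, a noncoding transcript at the Dlx5 and Dlx6 locus, was at 96.3 ± 7.4 CPM and at 0 counts with GFP, at least 1600-fold higher. Krt25, a hair follicle keratin (chromosome 11, 99315516 to 99322951), was at 219 ± 6.4 CPM, 10800-fold over GFP with a counting interval of 1940 to 427000. Nkx2-1, a factor of ventral forebrain, lung and thyroid, was at 22.9 ± 0.13 CPM and at least 376-fold higher. The hypothalamic factor Otp was 3160-fold higher (567 to 125000), and the forebrain factor Fezf2 at least 172-fold higher. Tbx5, which acts in heart and forelimb, was at least 156-fold higher, and Palmd at least 237-fold. Among the largest losses were Nphs1, the podocyte protein nephrin, at 1.68 ± 0.54 against 47.2 ± 1.6 CPM (-4.77), eosinophil peroxidase Epx (-4.98) and the collagen gene Col6a1 (-4.38). The fall of the metallothionein gene Mt2 (-5.2, adjusted p = 0.0213) was no longer called without Dlx2 replicate 1 (-4.51, adjusted p = 0.113) and without Dlx2 replicate 2 (-6.16, adjusted p = 0.0639).

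**Figure D1:**
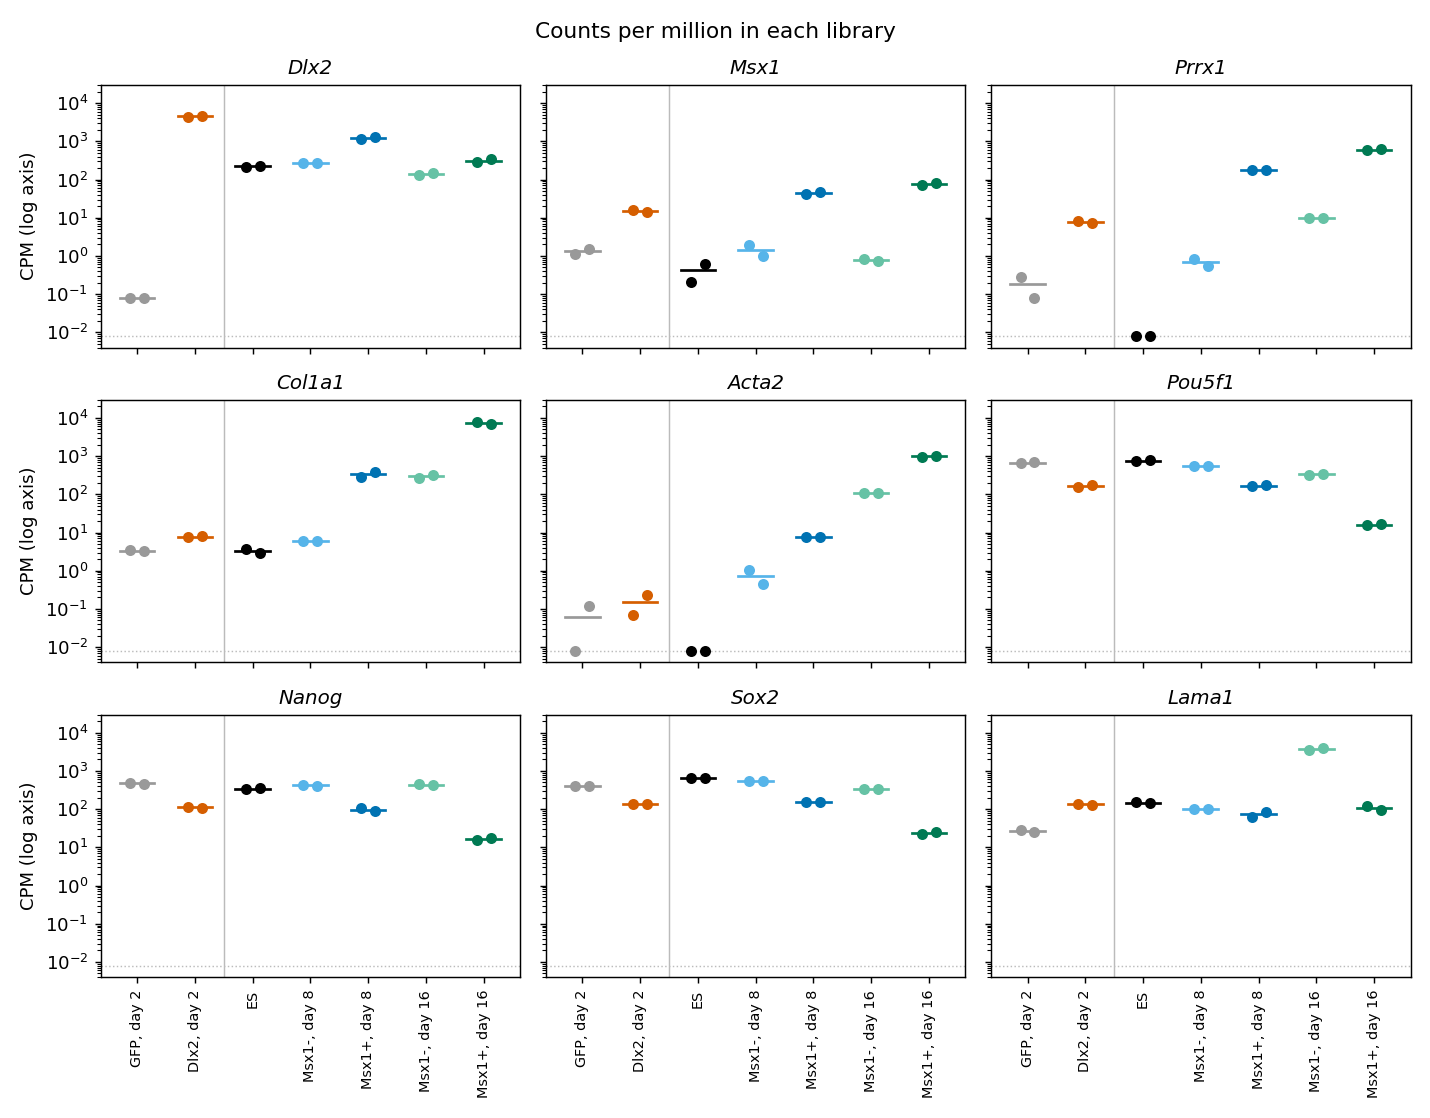
CPM per library (log axis) of 9 genes in the 7 groups, with bars at the group means, libraries with 0 counts drawn on the dotted line, and a vertical line between the day-2 table and the other table, which were scaled separately. Prrx1 stood at 7.8 CPM with Dlx2 at day 2 and at 176 and 611 CPM in Msx1-positive cells at days 8 and 16.

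At day 2, 9 gene groups rose and 5 fell of the 35 tested, and 0 of these 14 calls held in camera with an estimated correlation (adjusted p = 0.418 to 0.6). This form of camera has little power in a fit of 4 libraries. With it 2 lists had an unadjusted p below 0.05, and fry passed 31. A filter of at least 1 CPM in at least 4 libraries, which all day-2 libraries must then meet, left 4 of the 14 calls: naive pluripotency, core pluripotency, hypoxia and glycolysis, and ectomesenchyme with 10 of its genes still tested (adjusted p = 0.00449). With this filter the adjusted p was 0.0681 for odontogenic mesenchyme and for formative and primed pluripotency, 0.504 for neural crest and plate border specifiers, 0.059 for definitive and primitive endoderm, 0.131 for BMP response, 0.156 for peripheral neuron genes and 0.0578 for mitochondrially encoded transcripts. The Hox, 2-cell-like and histone lists had under 5 members left and were not tested. Of 29 ectomesenchyme genes 26 rose and 1 fell, with a list median of 3.82 (adjusted p = 7.91e-09, and 0.418 with an estimated correlation). Within it Dlx1 rose by 9.8 ± 0.12 to 202 ± 0.38 CPM, Pitx1 by 7.65 ± 0.15 to 86.5 ± 9.2 CPM and Msx2 by 4.38 ± 0.084 to 122 ± 7.6 CPM. Dlx5, a paralog of Dlx2 on another chromosome, rose by 6.26 ± 0.22. The odontogenic mesenchyme list, written for the tissue that forms dental pulp and dentine, had 11 of 16 genes higher and 2 lower (median 1.42, adjusted p = 0.00958), among them Barx1 at 51.8 ± 5.3 against 1.68 ± 0.65 CPM. Neural crest and plate border specifiers rose in 14 of 21 and fell in 4 (median 1.21, adjusted p = 0.0244): Sox9 rose by 2.75 ± 0.13, whereas Zic5, a gene of the plate border and of primed pluripotency, changed by -2.16. All 20 naive pluripotency genes fell (median -1.93, adjusted p = 5.79e-09), with Fgf4 at 31.6 ± 1.4 against 191 ± 0.47 CPM. Each of the 13 core pluripotency genes fell as well (median -1.38, adjusted p = 8.65e-06), Tdgf1 changing by -2.63 ± 0.05 and Utf1 by -2.47 ± 0.059. In the formative and primed list 3 of 15 rose and 10 fell, or 11 adjusted over the list alone (median -1.09, adjusted p = 0.007).

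The 8 further groups called at day 2 had an adjusted p of 0.418 to 0.6 with an estimated correlation, and of them only hypoxia and glycolysis stayed called with the stricter filter. Hox genes, which pattern the trunk, rose in 21 of 28 and fell in 2 (median 1.8, adjusted p = 0.000667), with Hoxb9 at 31.9 ± 2.6 against 3.2 ± 0.5 CPM. Definitive and primitive endoderm genes rose in 11 of 16 and fell in 2 (median 1.01, adjusted p = 0.00591), with Gata4 up by 3.41 ± 0.15 and the basement membrane gene Lama1 by 2.34 ± 0.068. The 7 tested members of the 2-cell-like list, transcripts of cleavage-stage embryos and of a rare ES cell state, all rose (median 4.54, adjusted p = 0.000907), Zscan4d by 139-fold (24.6 to 5500), although reads of these near-identical paralogs cannot be assigned with certainty. BMP response genes rose in 11 of 16 and fell in 3 (median 0.89, adjusted p = 0.0244), with Bmper at 18.8 ± 0.35 against 0.345 ± 0.37 CPM. Peripheral neuron genes rose in 7 of 11 and fell in 1 (median 0.87, adjusted p = 0.0244). Hypoxia and glycolysis genes fell in 13 of 17 and rose in 2 (median -0.89, adjusted p = 0.00106), with Pdk1 at 35.9 ± 0.83 against 254 ± 7.2 CPM. Mitochondrially encoded transcripts fell in 9 of 13 and rose in 1 (median -0.68, adjusted p = 0.0296, and 0.0637 without Dlx2 replicate 2), with mt-Co1 changing by -1.02 ± 0.057. Replication-dependent histone transcripts, most of which lack a poly(A) tail and so vary with library preparation, rose in 17 of 34, or 16 adjusted over the list alone, and fell in 1 (median 1.01, adjusted p = 0.00177), with Hist1h1c up by 3.07 ± 0.11.

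The mesenchymal matrix and EMT list was not called at day 2, where 12 members rose and 6 fell (adjusted p = 0.164). Its fibrillar collagen Col1a2 rose by 9.99 ± 0.11 to 1260 ± 20 CPM, while Fn1, which encodes fibronectin, changed by -1.01 ± 0.047 from a level of 1300 ± 11 CPM. Nor did the skeletal lists pass, with 6 chondrocyte genes higher and 1 lower (adjusted p = 0.109) and 4 osteoblast genes higher and 3 lower (adjusted p = 0.559). For other germ-layer groups the adjusted p was 0.102 for surface ectoderm and epidermis, 0.403 for neural genes, 0.466 for trophectoderm, and 0.466 for primitive streak and mesoderm. It was 0.0561 for endothelium, which was called lower without a filter on low counts (0.017) and without Dlx2 replicate 1 (0.027), Dlx2 replicate 2 (0.0197) or GFP replicate 1 (0.0399). It was 0.169 for blood, 0.413 for smooth muscle and pericyte, 0.652 for cardiac muscle, 0.936 for skeletal muscle and 0.523 for glia and melanocyte. Signalling and state lists that did not pass were WNT response (0.652), FGF and ERK response (0.466), retinoic acid response (0.413), p53 response (0.212), immediate early and dissociation stress (0.399), cell cycle (0.0676, and called lower without a filter, 0.0258) and epithelial adhesion (0.936). In the list of nuclear lamina and LAP2 partners 7 rose and 7 fell (adjusted p = 0.936).

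The day-2 contrast sets a Dlx2 line against a GFP line, and the uninduced EBs of both lines were not analysed here, so differences between the lines are part of it. Counts do not carry strand, and Tmpo, Pou5f1, Pdgfra, Tfap2a, Dlx1, Pitx1, Dlx6os1, Palmd, Mt2, Nphs1, Fn1 and mt-Co1 each overlap an exon of another annotated gene.

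At day 8 the comparison asked how cells with an active Msx1 reporter differ from those without. Of 22294 genes tested, 6772 were higher and 5415 lower in Msx1-positive cells, of which 3827 and 1317 changed by an absolute log2 of at least 1. With RLE scaling 6387 were higher and 5901 lower, so the excess of higher genes depends on the scaling. Msx1, on which the cells were sorted, was at 43.8 ± 4.2 against 1.46 ± 0.62 CPM, a difference of 4.89 ± 0.18 (adjusted p = 2.04e-10). Dlx2 was at 1200 ± 94 CPM in Msx1-positive and 270 ± 1.8 in Msx1-negative cells, a difference of 2.15 ± 0.084 (adjusted p = 3.63e-11). In ES cells, labelled untreated, it was at 220 ± 2 CPM. The mesenchymal genes Prrx1 (7.95 ± 0.11, adjusted p = 2.92e-15), Twist1 (2.85 ± 0.12, adjusted p = 3.9e-10) and Pdgfra (2.85 ± 0.07, adjusted p = 1.75e-13) were all higher in the positive fraction. Pou5f1 was lower there, at 168 ± 5.9 against 542 ± 3.4 CPM (-1.7 ± 0.055, adjusted p = 3.33e-12), as were Nanog (-2.12 ± 0.074) and Sox2 (-1.85 ± 0.064). Sox10 was higher by 2.11 ± 0.42 at 1.66 ± 0.45 CPM (adjusted p = 0.000605). Tfap2a was higher by 0.6 ± 0.15 (adjusted p = 0.00357), which was lost without Msx1-positive replicate 2 (0.41, adjusted p = 0.0768). Tmpo differed by -0.19 ± 0.052 (adjusted p = 0.00606).

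Osr1, Inhba and Dmp1 had the highest fitted gains at day 8. Their rank depends on the prior count, because each had 2 or fewer counts in Msx1-negative cells. Osr1 (chromosome 12, 9570116 to 9581500), of lateral plate and arch mesenchyme, was at 9.03 ± 0.13 CPM against 0 counts, at least 349-fold higher. Inhba, an activin subunit of tooth mesenchyme, was 963-fold higher (266 to 7960), and Dmp1, a matrix protein of osteocytes and odontoblasts, 962-fold (266 to 7950). Lhx8, a factor of oral mesenchyme, was at 17.5 ± 0.058 against 0.0878 ± 0.033 CPM. Postn, the matrix gene of periodontal ligament and periosteum, differed by 7.72 ± 0.3. The enamel matrix gene Ambn differed by 8.7 and the noncoding Dnm3os, host of mesenchymal microRNAs, by 8.84. Among the strongest losses were Ooep, a gene of the egg and early embryo, at 10.7 ± 0.39 against 91.4 ± 2.6 CPM (-3.09 ± 0.083), the pluripotency-linked noncoding genes Platr11 (-3.41) and Platr7 (-2.93), and Nphs1 (-2.94). Ubd (-3.56), Slc28a1 (-3.3) and Epp13 (-3.06) were also among them.

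Among gene groups at day 8, ectomesenchyme was higher in 31 of 33, or 32 adjusted over the list alone, and lower in 0 (median 3.36, adjusted p = 6.5e-13). Its endothelin receptor Ednra, which patterns the jaw, differed by 5.09 ± 0.11, and Dlx1 by 5.07 ± 0.093. Mesenchymal matrix and EMT genes were higher in 23 of 24 and lower in 1 (median 4.57, adjusted p = 1.77e-12, and 0.0639 with an estimated correlation). Cdh11 was at 155 ± 8.2 against 1.55 ± 0.27 CPM, and Col3a1 and Col1a2 differed by 6.57 ± 0.096 and 5.33 ± 0.084. Odontogenic mesenchyme was higher in 16 of 19 and lower in 2 (median 3.61, adjusted p = 1.01e-05, and 0.0639 with an estimated correlation), with Tnc at 207 ± 15 against 1.66 ± 0.4 CPM. Neural crest and plate border specifiers, a list that holds Msx1, were higher in 20 of 24 and lower in 3 (median 2.46, adjusted p = 4.72e-05, and 0.0874 with an estimated correlation), with Sox9 higher by 4.85 ± 0.12. Hox genes were higher in 35 of 39 and lower in 0 (median 2.23, adjusted p = 6.1e-08), Hoxb9 by 2.85 ± 0.12. Naive pluripotency genes were lower in 19 of 20 and higher in 0 (median -2.08, adjusted p = 1.46e-11), with differences of -2.66 ± 0.061 for Fgf4 and -2.41 ± 0.06 for Nr0b1. Core pluripotency genes were lower in 12 of 13 (median -1.62, adjusted p = 4.93e-08), with Tdgf1 at 204 ± 7 against 914 ± 0.1 CPM. Cell cycle genes were lower in 20 of 21 by a small amount (median -0.54, adjusted p = 2.44e-08), with Mcm3 at 303 ± 0.46 against 544 ± 0.039 CPM. The ectomesenchyme, Hox, naive, core and cell cycle calls are those that held with an estimated correlation.

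Calls of further groups at day 8 were all lost with an estimated correlation. BMP response genes were higher in 12 of 16 and lower in 1 (adjusted p = 3.07e-05, and 0.0874 with an estimated correlation), with Id1 at 76.3 ± 0.68 against 10.5 ± 0.66 CPM. Hypoxia and glycolysis genes were lower in 11 of 17 and higher in 2, or 3 adjusted over the list alone (adjusted p = 0.00134, and 0.0874 with an estimated correlation), with a difference of -1.45 ± 0.059 for Pdk1. Immediate early and dissociation stress genes, which cell sorting itself can induce, were higher in 10 of 14 and lower in 2 (adjusted p = 0.00337, and 0.19 with an estimated correlation), Junb by 2.26 ± 0.072. Smooth muscle and pericyte genes were higher in 7 of 12 and lower in 1 (adjusted p = 0.0133, and 0.178 with an estimated correlation), with Acta2 at 7.53 ± 0.14 against 0.749 ± 0.41 CPM. Osteoblast genes were higher in 9 of 13 and lower in 1 (adjusted p = 0.0133, and 0.178 with an estimated correlation). For chondrocyte genes, 8 of 14 higher and 1 lower, or 2 adjusted over the list alone, the values were 0.0172 and 0.259. Retinoic acid response (8 of 10 higher, 1 lower) had 0.01 and 0.149, and peripheral neuron genes (8 of 11 higher, 1 lower) 0.0172 and 0.151, and 0.069 with the filter of at least 1 CPM in at least 4 libraries. The 2-cell-like list was higher in 11 of 13 and lower in 0 (adjusted p = 0.0172, and 0.474 with an estimated correlation), with Zscan4a at 3.42 ± 0.55 against 1.8 ± 0.17 CPM.

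**Figure D2:**
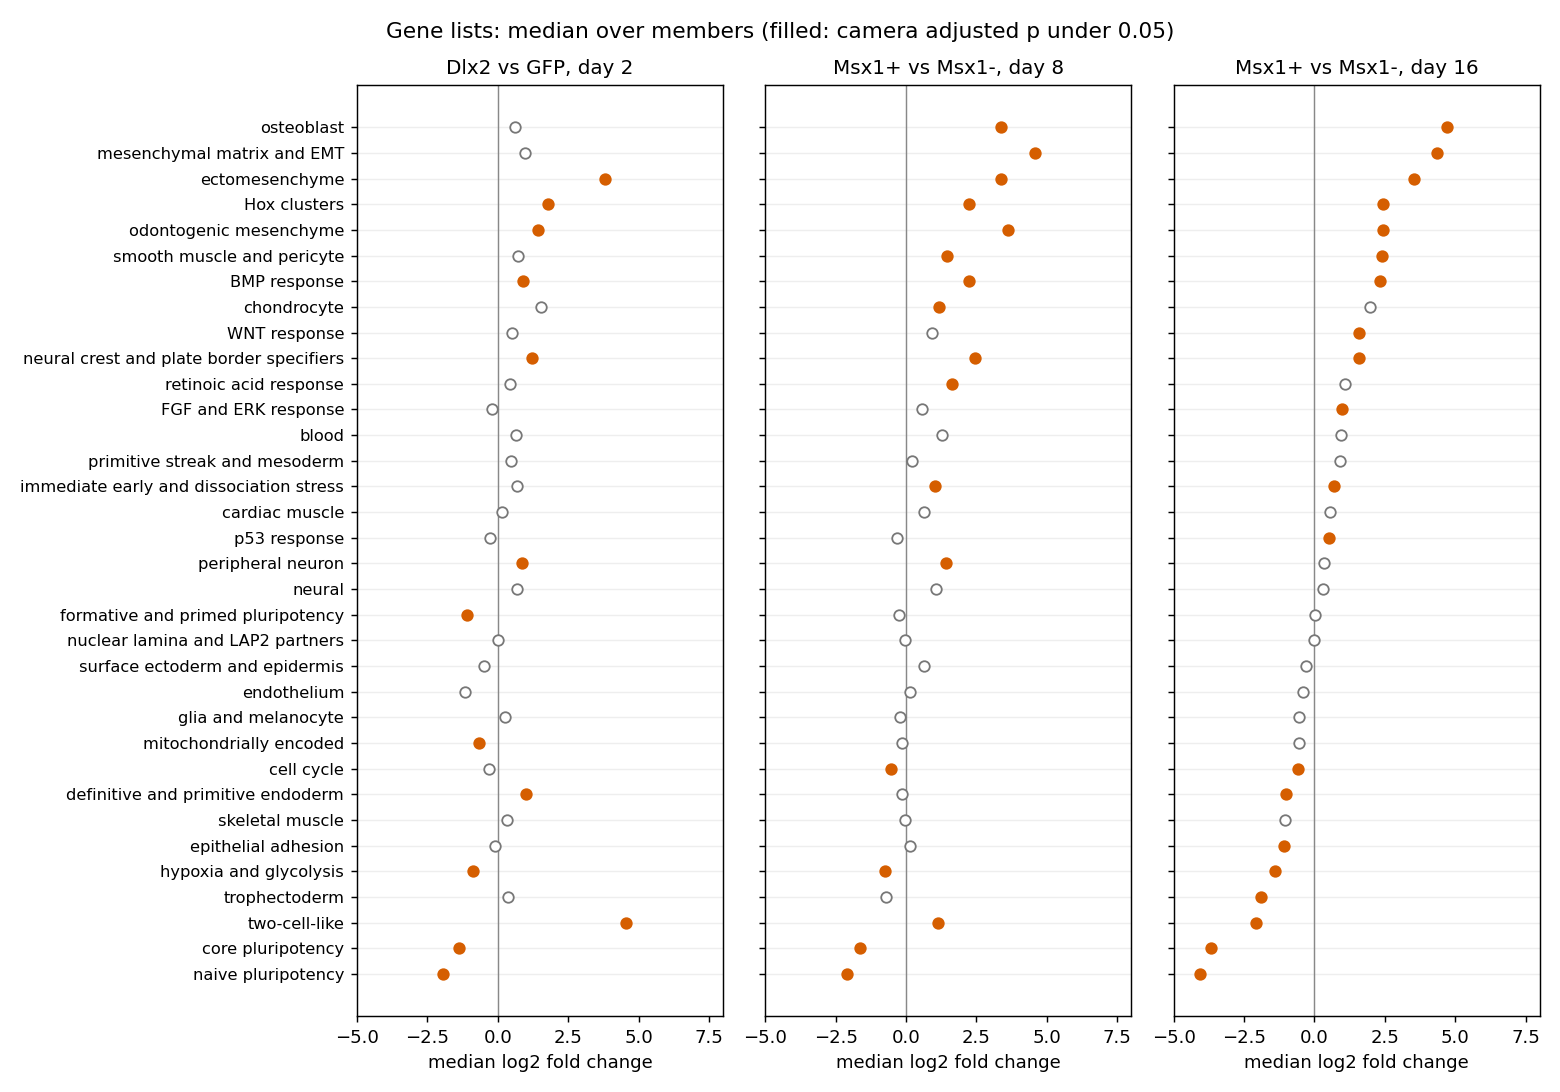
Median log2 fold change (x axis) of 34 gene lists in the day-2 comparison of Dlx2 with GFP and in the comparisons of Msx1-positive with Msx1-negative cells at days 8 and 16, with genes of 0 counts in a group at their bound. Filled points are lists with a camera adjusted p below 0.05, and the ectomesenchyme median was 3.82, 3.36 and 3.54 in the 3 comparisons.

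At day 16 Msx1-positive cells were again lower in Pou5f1, Nanog and Sox2 and higher in Prrx1 and Twist1. Of 22294 genes, 6943 were higher and 6904 lower in Msx1-positive cells. Msx1, the gene of the sort, was at 77.7 ± 5.6 against 0.785 ± 0.046 CPM. Pou5f1 was at 16.2 ± 0.38 CPM in positive and 334 ± 6.6 in negative cells, a difference of -4.37 ± 0.064 (adjusted p = 1.72e-15). Nanog differed by -4.72 ± 0.085 (adjusted p = 5.93e-15) and Sox2 by -3.88 ± 0.071 (adjusted p = 6.74e-15). Prrx1 was at 611 ± 0.77 against 10 ± 0.14 CPM (5.93 ± 0.08, adjusted p = 1.72e-15), and Twist1 was higher by 3.54 ± 0.12. Pdgfra was higher by 0.44 ± 0.062 only, at 200 ± 11 against 147 ± 5.4 CPM (adjusted p = 2.1e-05). Dlx2 was at 315 ± 37 against 139 ± 10 CPM (adjusted p = 1.35e-08), with ES cells at 220 ± 2. Not called were Tmpo (0.07, adjusted p = 0.267), Tfap2a (0.18, adjusted p = 0.336) and Sox10 (-0.42, adjusted p = 0.416).

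Ibsp and Dmp1 had the highest gains at day 16. Ibsp, the bone sialoprotein gene (chromosome 5, 104299171 to 104311469), was at 55.5 ± 3.3 CPM and 3400-fold higher (940 to 28100). Dmp1, its neighbour on chromosome 5, was at 251 ± 7.9 against 0.278 ± 0.069 CPM, a difference of 9.8 ± 0.13 (adjusted p = 1.72e-15). Lhx8 differed by 7.35 ± 0.22, and the remaining top genes were Gldn (8.82), Dio2 (7.87), Gria1 (7.84), Serpinb7 (7.78) and Il13ra2 (7.37). Among the genes furthest above the positive fraction in Msx1-negative cells were the gastrokine Gkn2, at 24.3 ± 2.8 against 0.0786 ± 0.065 CPM (-8.23 ± 0.42, adjusted p = 3.24e-09), its neighbour Gkn1 (-7.55) and the water channel gene Aqp8, at 101 ± 0.64 against 1.43 ± 0.29 CPM. Srgn, a proteoglycan of blood cells and of extraembryonic endoderm, was at 193 ± 15 against 2.93 ± 1.2 CPM. Ptk6 (-6.88), Trpv3 (-6.09), Ugt2b34 (-6.07) and Tcf23 (-6.06) were the others. As lists, blood (6 higher and 3 lower in Msx1-positive cells, or 8 and 4 adjusted over the list alone, adjusted p = 0.423) and surface ectoderm and epidermis (5 higher and 9 lower, or 7 and 9 adjusted over the list alone, adjusted p = 0.292) were not called.

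By group, all 24 mesenchymal matrix and EMT genes were higher at day 16 (median 4.35, adjusted p = 2.74e-13), with Lox, which crosslinks collagen, at 305 ± 9.2 against 4.43 ± 0.62 CPM and Col6a2 at 303 ± 13 against 7.01 ± 0.43. Ectomesenchyme was higher in 31 of 33 and lower in 1 (median 3.54, adjusted p = 1.88e-11). Odontogenic mesenchyme was higher in 16 of 19 and lower in 1 (median 2.43, adjusted p = 4.29e-06), with Inhba higher by 5.2 ± 0.093, and Hox genes in 35 of 39 with 0 lower (median 2.43, adjusted p = 7.38e-09). Naive pluripotency genes were lower in 19 of 20 and higher in 1 (median -4.05, adjusted p = 1.99e-10), with Esrrb at 21.1 ± 0.077 against 371 ± 4.3 CPM and a difference of -5.37 ± 0.077 for Fgf4. Core pluripotency genes were lower in 12 of 13 (median -3.66, adjusted p = 4.13e-08). Cell cycle genes were lower in 20 of 21 (median -0.6, adjusted p = 1.28e-06), with Ccnb1 at 167 ± 1.8 against 371 ± 6 CPM, and hypoxia and glycolysis genes in 14 of 17 with 2 higher (median -1.41, adjusted p = 1.89e-05). These 8 groups held with an estimated correlation, with adjusted p from 0.0334 to 0.0482.

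The other 12 calls at day 16 did not hold with an estimated correlation. All 12 smooth muscle and pericyte genes were higher (adjusted p = 6.09e-06, and 0.0526 with an estimated correlation), with Acta2 at 1000 ± 41 against 111 ± 0.19 CPM. Osteoblast genes were higher in 11 of 13 and lower in 1 (adjusted p = 0.000251, and 0.0776 with an estimated correlation): the bone factor Sp7 was at 32.7 ± 0.27 against 0.859 ± 0.058 CPM, while Alpl, which ES cells also express, was at 18.1 ± 2.4 against 187 ± 0.52 CPM. Epithelial adhesion genes were lower in 17 of 18 (adjusted p = 3.17e-06, and 0.0756 with an estimated correlation), with Epcam at 44 ± 2.9 against 175 ± 4.8 CPM and Cdh1 at 172 ± 0.63 against 407 ± 22. Definitive and primitive endoderm genes were lower in 12 of 20 and higher in 2 (adjusted p = 0.00101, and 0.0633 with an estimated correlation), with Col4a1 at 850 ± 81 against 6610 ± 100 CPM, Sox17 at 9.56 ± 1.2 against 83.2 ± 3.6 and Gata4 at 39.4 ± 0.25 against 164 ± 1.5. Trophectoderm genes were lower in 9 of 13 and higher in 3 (adjusted p = 0.0106, and 0.146 with an estimated correlation), with Krt7 at 27.6 ± 0.35 against 102 ± 3.3 CPM. All 13 2-cell-like genes were lower (adjusted p = 4.1e-05, and 0.21 with an estimated correlation), with Zscan4c at 3.56 ± 0.45 against 17.3 ± 2.6 CPM.

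BMP, WNT, and FGF and ERK response lists were called higher in Msx1-positive cells at day 16. For BMP response (12 of 16 higher, and 2 lower, or 3 adjusted over the list alone) the adjusted p was 0.000372, and 0.101 with an estimated correlation. It was 0.0106 and 0.101 for WNT response (10 of 14 higher, 2 lower), and 0.0106 and 0.291 for FGF and ERK response (8 of 12 higher, 1 lower). Neural crest and plate border specifiers were higher in 18 of 24 and lower in 3 (0.000876 and 0.107). Immediate early and dissociation stress genes were higher in 10 of 14, or 11 adjusted over the list alone, and lower in 1 (0.00114 and 0.146), with Egr1 at 559 ± 27 against 116 ± 3 CPM. The p53 response was higher in 10 of 16 and lower in 3 (0.0268 and 0.21), Cdkn1a by 1.38 ± 0.057, a call lost with the filter of at least 1 CPM in at least 4 libraries (adjusted p = 0.0693) and with only the compared groups in the fit (adjusted p = 0.0536). Endothelium was not called, with 4 genes higher and 7 lower (adjusted p = 0.294), although Pecam1, also a gene of ES cells, was lower at 9.63 ± 0.61 against 135 ± 4 CPM.

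Counts of the sorted cells rest on 2 libraries per group, and immediate early genes differed between fractions at both days, so effects of dissociation and sorting on transcripts are not separated from these contrasts. Exons of another annotated gene overlap those of Dnm3os, Ednra, Tnc, Col3a1, Lox, Krt7, Sox17, Col4a1, Junb, Cdkn1a, Dio2 and Nphs1.

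Whether the difference between fractions changed with time was tested directly, as the day-16 effect minus the day-8 effect. It was called for 2294 genes in the positive and 4090 in the negative direction, of which 414 and 2579 by an absolute log2 of at least 1. With RLE scaling 2821 and 3829 were called. The pluripotency factors parted further, by -2.67 for Pou5f1, -2.6 for Nanog and -2.03 for Sox2. The differences of Prrx1 (-2.02), Pdgfra (-2.41 ± 0.092, adjusted p = 2.56e-10) and Dlx2 (-0.97 ± 0.12, adjusted p = 2.09e-05) became smaller on the log2 scale. Prrx1 rose in both fractions, from 176 to 611 CPM in Msx1-positive and from 0.698 to 10 CPM in Msx1-negative cells, so its levels moved further apart in CPM. For Pdgfra the level in Msx1-negative cells went from 17.3 ± 0.74 to 147 ± 5.4 CPM. Clec11a, a growth factor for bone-forming cells, differed between fractions by -0.66 at day 8 and by 4.03 at day 16, an interaction of 4.68. For Insc (4.28) and Gabra3 (3.96) the day-8 difference was not called (0.05 and 0.54, adjusted p = 0.856 and 0.0699), and the day-16 difference was 4.33 and 4.5. The call for Ibsp (7.22 ± 1.3, adjusted p = 0.000971) was lost without day-8 Msx1-negative replicate 1 (2.32, adjusted p = 0.927), as was that for the proteoglycan gene Ogn (4.39 ± 0.71), whose size stayed near (3.53, adjusted p = 0.058). In the negative direction stood Gkn2 (-10.85), Gkn1 (-8.41), Osr1 (-8.19), Ugt2b34 (-7.91) and Wfdc1 (-7.28). The fitted sizes for Ibsp, Gkn2, Gkn1 and Osr1 depend on the prior count, because each had 2 or fewer counts in a group. The interaction of Tmpo (0.26 ± 0.074, adjusted p = 0.0157) was no longer called without either day-8 Msx1-negative library (0.27 and 0.29, adjusted p = 0.0642 and 0.052) and without day-16 Msx1-negative replicate 1 (0.26, adjusted p = 0.0617).

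**Figure D3:**
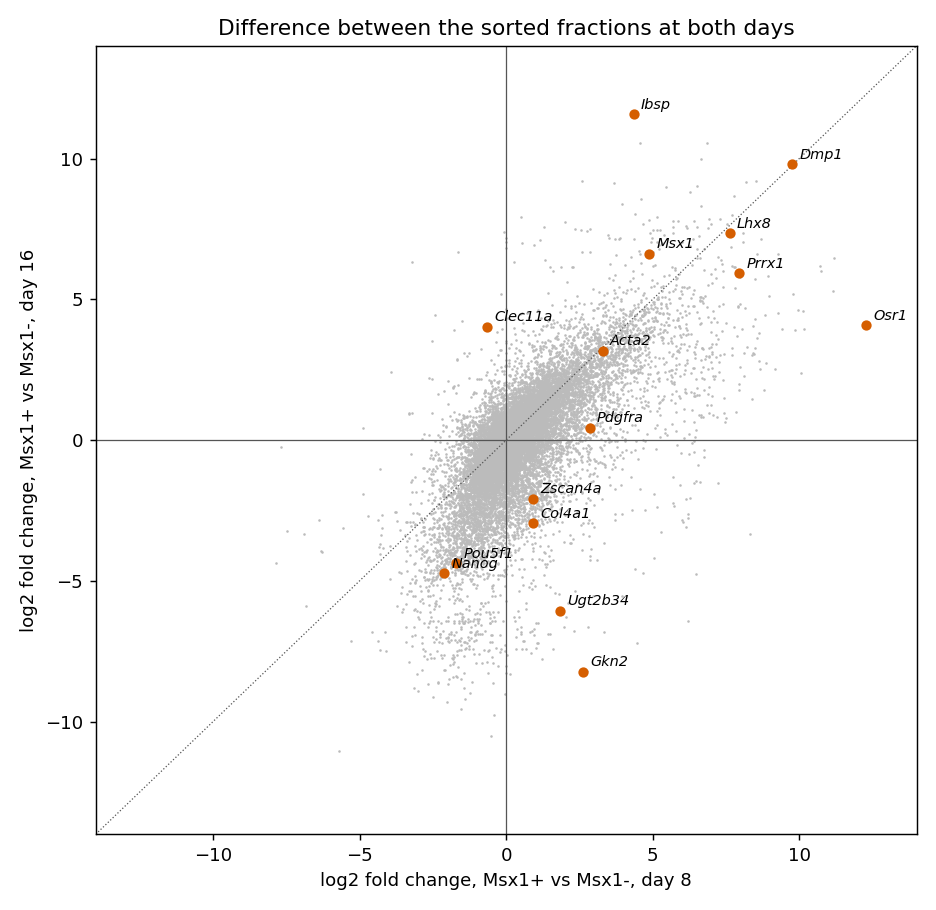
Log2 fold change of Msx1-positive against Msx1-negative cells at day 8 (x axis) and at day 16 (y axis) for the tested genes, with the dotted line at equal values and named genes labelled. Ibsp and Clec11a lie above the line, and Osr1, Gkn2, Ugt2b34 and Pdgfra below it.

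As groups, 15 lists were called for this interaction, and 0 of them held in camera with an estimated correlation (adjusted p = 0.0728 to 0.296). With it 8 lists had an unadjusted p below 0.05, and fry passed 26. Towards Msx1-negative cells went naive pluripotency (18 of 20 with 2 the other way, adjusted p = 3.69e-09), core pluripotency (12 of 13, 1.21e-08) and the 2-cell-like list (13 of 13, 3.09e-08). The same direction was taken by epithelial adhesion (16 of 18, or 17 adjusted over the list alone, 1.21e-08), definitive and primitive endoderm (12 of 20, with 1 the other way adjusted over the list alone, 0.000485) and surface ectoderm and epidermis (12 of 18, or 14 adjusted over the list alone, 0.000338). Trophectoderm (10 of 13 against 1, or 11 against 2 adjusted over the list alone, 0.00112), endothelium (7 of 14 against 1, 0.0266), and neural crest and plate border specifiers (13 of 24 against 4, or 5 adjusted over the list alone, 0.0342) did too. Hypoxia and glycolysis followed (14 of 17 against 1, or 15 adjusted over the list alone, 0.000101). Towards Msx1-positive cells went the p53 response (10 of 16, or 12 against 1 adjusted over the list alone, 1.58e-07), smooth muscle and pericyte (7 of 12 against 1, or 2 adjusted over the list alone, 0.0168) and osteoblast genes (6 of 13 against 3, 0.0266). WNT response (6 of 14 against 2, or 7 adjusted over the list alone, 0.0342) and FGF and ERK response (4 of 12 against 1, or 5 adjusted over the list alone, 0.0062) went with them. With the filter of at least 1 CPM in at least 4 libraries the adjusted p was 0.143 for osteoblast genes, and 0.0767 for smooth muscle and pericyte and for WNT response. The WNT call was also lost with RLE scaling (0.0586) and without replicate 1 of day-16 Msx1-positive (0.0508) or Msx1-negative cells (0.0855). The call of neural crest and plate border specifiers was lost with ES libraries in the fit (0.116) and without day-8 Msx1-positive replicate 2, either day-16 Msx1-positive library or day-16 Msx1-negative replicate 2 (0.0508 to 0.0816), and that of endothelium without day-8 Msx1-negative replicate 1 (0.078) or day-16 Msx1-negative replicate 2 (0.113). Ectomesenchyme was not called, with 9 members towards Msx1-positive and 13 towards Msx1-negative cells (adjusted p = 0.69), and neither was mesenchymal matrix and EMT (7 and 7, adjusted p = 0.421).

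Most genes called at both days differed in the same direction. Of 10017 genes called at day 8 and at day 16, 9425 (94.1%) went the same way, and the 5212 higher at both days compare with 2109 if calls were independent. Of 8635 genes called in the day-2 comparison and at day 8, 7420 (85.9%) went the same way, with 3834 higher in both against 2062.3 for independent calls. For day 2 and day 16 it was 6633 of 8948 (74.1%). These comparisons share no library, and genes are not independent replicates.

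Within Msx1-positive cells, the time from day 8 to day 16 raised 4713 genes and lowered 5526, or 5063 and 5115 with RLE scaling. Acta2, the smooth muscle actin (chromosome 19, 34241090 to 34255590), went from 7.53 ± 0.14 to 1000 ± 41 CPM, a change of 7.05 ± 0.12 (adjusted p = 3.88e-13). Ogn rose by 7, the enteric actin gene Actg2 by 6.7, the tendon and ligament proteoglycan Aspn by 5.73 and Ibsp by 5.66. Dmp1 rose by 3.92 ± 0.081 and Inhba by 3.72 ± 0.083. The largest falls were of Mt3 (-4.47), the retinal and spinal factor Foxn4 (-4.31), the cholinergic transporter gene Slc18a3 (-4.05), Pla2g10 (-3.96) and Npas1 (-3.96). Dlx2 fell by 1.94 on the log2 scale (adjusted p = 2.08e-10) while Prrx1 rose by 1.8 and Msx1 by 0.82 (adjusted p = 0.000176). Pou5f1 changed by -3.37. Tmpo was not called (0.09, adjusted p = 0.192), and Tfap2a was called only without day-8 Msx1-positive replicate 1 (-0.48, adjusted p = 0.0387, against -0.31 and 0.104 with all libraries).

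By group, all 24 mesenchymal matrix and EMT genes rose in Msx1-positive cells (median 2.05, adjusted p = 9.54e-16), as did Hox genes in 35 of 39, or 36 adjusted over the list alone (median 2.05, adjusted p = 2.37e-12), and smooth muscle and pericyte genes in 11 of 12 (median 2.24, adjusted p = 8.37e-08). Definitive and primitive endoderm genes rose in 14 of 20 and fell in 2 (median 1.32, adjusted p = 2.65e-05). Naive pluripotency genes fell in 18 of 20 and rose in 1 (median -2.52, adjusted p = 2.67e-10), with Esrrb changing by -3.27 ± 0.059, and core pluripotency genes fell in 12 of 13 (median -2.72, adjusted p = 1.51e-09). These 6 groups held with an estimated correlation. All 14 immediate early and dissociation stress genes rose (adjusted p = 5.53e-08, and 0.0663 with an estimated correlation). Ectomesenchyme rose in 21 of 33, or 22 adjusted over the list alone, and fell in 4 (adjusted p = 5.98e-05, and 0.0937 with an estimated correlation), and odontogenic mesenchyme rose in 13 of 19 and fell in 3 (0.00118 and 0.0937). Cell cycle genes fell in 15 of 21, or 16 adjusted over the list alone (0.000244 and 0.0578). Of the 7 remaining calls, which had 0.0937 to 0.22 with an estimated correlation, hypoxia and glycolysis fell (0.0151). The p53 (0.000304), WNT (0.00444), retinoic acid (0.00967) and BMP (0.0252) responses, osteoblast genes (0.00554), and primitive streak and mesoderm (0.0364) rose. With the filter of at least 1 CPM in at least 4 libraries the calls of primitive streak and mesoderm (0.104) and BMP response (0.0524) were lost, the former also with only the compared groups in the fit (0.0549).

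Within Msx1-negative cells 4399 genes rose and 3974 fell from day 8 to day 16, of which 2156 and 296 by an absolute log2 of at least 1. Among the highest gains were Gkn2, at 24.3 ± 2.8 CPM and 1400-fold higher (389 to 11600), and Gkn1, 364-fold higher (101 to 3010). The embryonic globin gene Hbb-y was 827-fold higher (148 to 32700), Inhba 345-fold (95.1 to 2850), and Ugt2b34 rose by 8.38 ± 0.41. The strongest falls were smaller, of Exoc3l (-2.1), Enpp2 (-1.7), Ina (-1.68), Aoah (-1.65) and Jph4 (-1.64). Definitive and primitive endoderm genes rose in 17 of 20 and fell in 0 (median 2.94, adjusted p = 8.39e-11): Col4a1 went from 183 ± 0.62 to 6610 ± 100 CPM, Sox17 rose by 4.75 ± 0.11 and Gata4 by 3.75 ± 0.086. This call and that of the Hox genes, 31 of 39 higher or 32 adjusted over the list alone (median 1.78, adjusted p = 3.26e-10), held with an estimated correlation. Pou5f1 changed by -0.7, and Nanog was not called (0.04, adjusted p = 0.746). Prrx1 rose by 3.82, Pdgfra by 3.08, and Dlx2 changed by -0.96 ± 0.083 (adjusted p = 5.24e-07). The fall of Msx1 (-0.91, adjusted p = 0.0184) was lost without day-8 Msx1-negative replicate 1, which cut its size to -0.39 (adjusted p = 0.259). It was no longer called in 4 further alternatives that left it between -0.85 and -0.98: only the compared groups in the fit (adjusted p = 0.0633), ES libraries in it (0.0777), and without either day-16 Msx1-negative replicate (0.0792 and 0.122). The fall of Tmpo (-0.17, adjusted p = 0.0174) was no longer called without any of the 4 Msx1-negative libraries (-0.16 to -0.2, adjusted p = 0.0565 to 0.114).

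The other 19 groups called in Msx1-negative cells over time had 0.0521 or more with an estimated correlation. Mesenchymal matrix and EMT rose in 20 of 24 and fell in 1 (median 2.05, adjusted p = 7.77e-12, and 0.0521 with an estimated correlation), where Col3a1 went from 2.27 ± 0.26 to 115 ± 6.5 CPM. Smooth muscle and pericyte genes rose in 11 of 12, or 12 adjusted over the list alone (adjusted p = 5.46e-07, and 0.0521 with an estimated correlation), with Acta2 at 111 ± 0.19 against 0.749 ± 0.41 CPM. Ectomesenchyme rose in 24 of 33 and fell in 3 (5.46e-07 and 0.0595). All 13 2-cell-like genes rose (median 3.34, 1.11e-09 and 0.109), Zscan4a by 3.34 ± 0.18, and 11 of 13 trophectoderm genes rose with 0 lower (6.5e-06 and 0.0521). All 10 retinoic acid response genes rose (3e-05 and 0.0521). Core pluripotency genes fell in 12 of 13 by a smaller step than in Msx1-positive cells (median -0.69, 2.7e-07 and 0.0521), and naive pluripotency genes fell in 14 of 20, or 15 adjusted over the list alone, and rose in 1, or 2 adjusted over the list alone (median -0.35, 0.000143 and 0.0521). Cell cycle (1.85e-05), formative and primed pluripotency (0.000454) and FGF and ERK response (0.00071) also fell. Rises were called for immediate early and dissociation stress (3e-05), epithelial adhesion (0.000289), BMP response (0.000454), surface ectoderm and epidermis (0.00601), odontogenic mesenchyme (0.00619), neural crest and plate border specifiers (0.00686), endothelium (0.0209) and cardiac muscle (0.0414). The call of endothelium was lost with the filter of at least 1 CPM in at least 4 libraries (0.0558), and that of cardiac muscle with only the compared groups in the fit (0.0797) and without day-16 Msx1-negative replicate 2 (0.116). Blood was not called (adjusted p = 0.0512), and passed with RLE scaling (0.0452), without a filter (0.0182), with the stricter filter (0.00764), with ES libraries in the fit (0.0301) and without day-8 Msx1-negative replicate 2 (0.00584).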

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

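The tests of explanations in this part were chosen after the values had been seen, while the test of the difference between the day-8 and day-16 effects was fixed beforehand.

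The difference between Msx1-positive and Msx1-negative cells was not the same at both days, which drew attention to 6384 genes whose day-16 effect differed from their day-8 effect by a direct test. Their strongest members are of several kinds. Ibsp (7.22), Clec11a (4.68) and Ogn (4.39) encode proteins of bone or fibrous matrix or act on bone-forming cells, and gained in Msx1-positive cells. Insc (4.28) and Gabra3 (3.96) were higher in positive cells at day 16 (4.33 and 4.5) and not called at day 8. Mean levels of Clec11a were 1.1 and 1.75 CPM in positive and negative cells at day 8, and 16.5 and 1.01 CPM at day 16. Those of Ibsp were 1.09 and 0.0486 CPM at day 8, and 55.5 and 0.0164 CPM at day 16. Without day-8 Msx1-negative replicate 1 the interaction of Ibsp was 2.32 and that of Ogn 3.53, and neither was called. For Ibsp the level in Msx1-negative cells is so near 0 that the fitted size depends on the prior count. The smaller value therefore does not show that 1 library made the difference, and the size of this interaction is uncertain.

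In the opposite direction Gkn2 (-10.85), Gkn1 (-8.41), Ugt2b34 (-7.91) and Wfdc1 (-7.28) were at low levels in 3 of the sorted groups and higher in day-16 Msx1-negative cells, at 24.3, 6.29, 15 and 10.7 CPM. Osr1 (-8.19) was found in Msx1-positive cells alone at day 8, at 9.03 CPM against 0 counts, and in both fractions at day 16, at 22.3 and 1.31 CPM. The fitted sizes for Ibsp, Gkn2, Gkn1 and Osr1 depend on the prior count, because 2 or fewer counts stand in a group.

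ES cells are outside the fixed comparisons that were run, and they drew attention because Dlx2 was at 220 ± 2 CPM in their libraries, which the labels call wild type and untreated. In induced GFP EBs of the day-2 table, scaled separately, Dlx2 was at 0.081 ± 0.00027 CPM. Compared with ES cells, Dlx2 differed by 2.45 and 0.52 in Msx1-positive cells at days 8 and 16. In Msx1-negative cells it differed by 0.3 and -0.67. By the edgeR test it was thus called higher than the unexplained ES level in day-16 Msx1-positive cells, at 315 CPM (adjusted p = 1.26e-05). The same held for day-8 Msx1-negative cells, at 270 CPM (adjusted p = 0.00646). In day-16 Msx1-negative cells, at 139 CPM, it was called lower (adjusted p = 1.49e-06). Reads carried over from the sorted libraries of the same table are argued against: the level in ES cells was 18.3% of that in day-8 Msx1-positive cells for Dlx2, but a median of 0.575% and at most 5.83% over the 7 ectomesenchyme genes with at least 50 CPM there. Reads of other Dlx genes counted as Dlx2 may contribute but remain undecided, since those genes together had 2.63 CPM in ES cells, which does not show where their reads fell. Transcription from an inducible construct without doxycycline could also give these counts: Dlx2 was 2830 times the level of its neighbour Dlx1, yet counts per gene do not separate the construct from the endogenous gene, and uninduced EBs were not analysed here. No biological explanation was tested.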

How the results depend on the processing

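Scaling by library size alone, ES libraries in the fit and the comparisons with ES cells were added after the data had been seen, and the other alternatives were fixed beforehand. No called direction of a named gene reversed in an alternative. Library size alone was applied to medians. Of the counts of called genes 116 stayed within 1.5 times the value reported and 10 did not, and of the counts of called lists 97 did and 19 did not, leaving out single libraries included. RLE scaling, DESeq2, no filter, the compared groups alone, ES libraries in the fit and a threshold of 0.01 moved no total of called genes by more than that. Higher and lower genes were not counted apart in this check. For the genes that the naming rule gives, 3055 values kept their direction and side of the threshold, 30 were no longer called and 4 were newly called. These changes concern Sox10, Mt2, Msx1, Tfap2a, Tmpo, Ibsp, Ogn, Nanog, Sox2 and Twist1, and are given beside each value that the text prints.

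An absolute log2 change of at least 1 left 4989 genes at day 2, 5144 between fractions at day 8, 7281 at day 16, 2993 for the difference between these effects, 4077 over time in Msx1-positive and 2452 in Msx1-negative cells. Against ES cells it left 6971 for day-8 Msx1-positive, 2452 for day-8 Msx1-negative, 10124 for day-16 Msx1-positive and 4845 for day-16 Msx1-negative cells. The alternative removes small changes by construction.

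With an estimated correlation between genes camera called 0 lists at day 2, 5 at day 8, 8 at day 16, 0 for the difference between the effects, and 6 and 2 over time in Msx1-positive and Msx1-negative cells. Against ES cells it called 9, 9, 10 and 13 lists in the order given above. Camera in that form also has fewer degrees of freedom, set by the libraries of the fit, so lost calls do not isolate the correlation. Fry called 31, 27, 32, 26 and 28 lists in the first 5 of the fixed comparisons, and 32 each for day-8 Msx1-positive, day-16 Msx1-positive and day-16 Msx1-negative cells against ES cells. It tests another question than camera, without other genes as a background. With a filter of at least 1 CPM in at least 4 libraries 4 lists were called at day 2, where this demands a count in every library and so removes genes that only 1 group expressed. Apart from these constructions the cause was not tested.

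Leaving out each library in turn, where the remaining library is assumed to vary like those of other groups, gave 10490 to 12283 genes and 14 to 15 lists at day 2. It gave 10585 to 11238 genes and 17 lists at day 8, 12229 to 12600 and 20 at day 16, and 5267 to 6081 and 13 to 16 for the difference between the effects. Over time it gave 8685 to 9212 genes and 17 lists in Msx1-positive and 6329 to 6647 and 20 to 22 in Msx1-negative cells. Against ES cells it gave 12454 to 12887 genes and 18 lists, 5527 to 5963 and 19 to 20, 14876 to 14980 and 19 to 20, and 10187 to 10375 and 19 to 21.

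With the replicate number as a replicate block 11959 genes were called at day 8, 13682 at day 16, 6090 for the difference, and 9986 and 8124 over time. Deviations of replicates from their group means correlated across genes by -0.39 to 0.607 between the sorted groups, so shared numbers do not point to a shared preparation in every pair. At day 2 no replicate block was fitted, because the columns match a group but no single labelled sample and the numbers in their names were not used to link a Dlx2 to a GFP library.

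In simulated data with the measured depth and the spread fitted over genes of like level, 89.6% of genes with a 1.5-fold change were recovered at day 2, 74.6% at day 8 and 68.7% at day 16, and 91, 95.5 and 88.1% of those with a 2-fold change, while 1.06, 3.24 and 5% of calls were false. For day-8 Msx1-positive against ES cells 65.7 and 89.6% were recovered, and 5.56% of calls were false. Camera called 20 of 20 moved lists and 0 of 20 unmoved lists there, with no correlation between genes simulated. Few genes were changed in the simulation: at day 2 each fold was put into 66 or 67 genes, and 17935 had no change. The changed genes were drawn only from those with a mean of at least 1 CPM. Recovery of changes in genes at lower levels, which were also tested in the measured data, was therefore not simulated. In the measured data 67.2% of genes were called at day 2. Scaling and the share of false calls were therefore not tested under so many changes.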

Other observations

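The comparisons with ES cells and the tests of explanations in this part were chosen after the data had been seen.

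Against ES cells, Msx1-negative cells were lower in Pou5f1 and Sox2 and higher in Nanog. Pou5f1 was at 762 ± 17 CPM in ES cells, and at 542 ± 3.4 and 334 ± 6.6 in Msx1-negative cells at days 8 and 16 (-0.49 and -1.19). Sox2 was at 651 ± 6.5 CPM in ES cells, and at 554 ± 9.3 and 343 ± 3.1 (-0.23 and -0.92), the day-8 call being lost without day-8 Msx1-negative replicate 2 (-0.21, adjusted p = 0.0607). Nanog was higher than in ES cells at both days, at 425 ± 13 and 435 ± 14 against 348 ± 22 CPM (adjusted p = 0.0041 and 0.000838), although the day-8 call was lost without ES replicate 1 (0.23, adjusted p = 0.0658). Core pluripotency genes were not called as a group at day 8, with 4 higher and 5 lower (adjusted p = 0.206), and were lower in 12 of 13 and higher in 1 at day 16 (adjusted p = 2.01e-05, and 0.0256 with an estimated correlation). Immediate early and dissociation stress genes were higher than in ES cells in 6 and lower in 6 of 14 at day 8 (adjusted p = 0.558), and higher in 9 and lower in 4, or 5 adjusted over the list alone, at day 16 (adjusted p = 0.0281, 0.251 with an estimated correlation and 0.0609 with only the compared groups in the fit). Of them Fosb was at 48.1 ± 1.4 and 263 ± 3.1 CPM against 0.729 ± 0.022 (6.04 and 8.49), so effects of dissociation and sorting are not separated from the comparisons with ES cells. Nor are those of doxycycline, of growth as EBs and of time in culture, since the ES cells are labelled untreated. In all, 7551 genes differed from ES cells at day 8 (4280 higher, 3271 lower) and 11920 at day 16 (6407 higher, 5513 lower). An absolute log2 change of at least 1 left 1879 and 573, and 3790 and 1055.

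Definitive and primitive endoderm genes were higher than in ES cells in 16 of 20 at day 8 with 1 lower (adjusted p = 6.81e-09, and 0.0171 with an estimated correlation), and in 17 with 0 lower at day 16 (6.8e-10 and 0.00982). The basement membrane collagen gene Col4a1 was at 6610 ± 100 CPM in day-16 Msx1-negative cells against 74.6 ± 2.1 in ES cells (6.47 ± 0.079), and the endocytic adaptor gene Dab2 at 203 ± 5.2 against 1.49 ± 0.13. Trophectoderm genes were higher in 12 of 13 with 0 lower at both days (adjusted p = 2.17e-10 and 2.68e-08, and 0.0171 and 0.022 with an estimated correlation). Plac1, a placental gene, was at 12.4 ± 0.51 and 32.6 ± 4.4 CPM against 0 counts, at least 426-fold and 1120-fold higher. Srgn was 9920-fold higher at day 16 (2750 to 81900). All 13 2-cell-like genes were higher (adjusted p = 2.23e-10 and 4.48e-09, and 0.0496 and 0.0462 with an estimated correlation), with the limit on near-identical paralogs. Among the strongest losses were the LIF target Socs3 and the BMP target Id1 at day 8 (-3.53 and -3.13) and the FGF target Spry4 at day 16 (-3.25). Exons of Col4a1 and Dab2 overlap those of another gene.

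Msx1-positive cells differed from ES cells in 13843 genes at day 8 (7784 higher, 6059 lower) and 15976 at day 16 (8395 higher, 7581 lower). An absolute log2 change of at least 1 left 5024 higher and 1947 lower at day 8, and 5891 and 4233 at day 16. Prrx1 had 0 counts in ES cells and was at least 6030-fold and 21000-fold higher at days 8 and 16, and Postn at least 2480-fold and 40700-fold. Immediate early and dissociation stress genes were higher in 10 and lower in 3 of 14 at day 8 (adjusted p = 0.0092, and 0.213 with an estimated correlation) and higher in 11 and lower in 1 at day 16 (adjusted p = 0.000391, and 0.114 with an estimated correlation), with Fosb at 124 ± 8.5 and 390 ± 15 CPM. Scaling by library size alone put the median of all genes at 0.3 at day 8 and 0.138 at day 16, against 0.114 and 0.068 with TMM, and at 0.17 for day-16 Msx1-negative cells, against 0.065.

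Mesenchymal transcripts were also found in day-16 Msx1-negative cells, where Col1a1 was at 298 ± 32 CPM against 6.01 ± 0.029 at day 8. Carry-over of Msx1-positive cells of average content is argued against as the only source of Col1a1 and Acta2. Msx1 itself stood at 1.01% of its level in positive cells, at most 1.11% across libraries, while Col1a1 stood at 4.04% and Acta2 at 11.1%. The median over the 24 mesenchymal matrix genes was 4.9% and all 24 lay above Msx1. The ectomesenchyme median was 8.56% and 32 of 33 members lay above Msx1. These medians do not decide, because the cells were sorted on Msx1 and levels in other cells were not subtracted. Twist1, for one, was at 4.94 CPM in ES cells and at 131 in day-16 Msx1-positive cells. Mesenchymal cells whose reporter stayed below the gate remain possible, but another cell type that expresses the same genes would give the same values. The shares were uneven, with Prrx1 at 1.64% and Dmp1 at 0.111%. A change of the sorted cells' identity by day 16, as a biological explanation, stays open and untested.

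At day 2 most tested genes differed between the Dlx2 and the GFP line. A copy difference of a whole autosome, carried by all cells of a line, is argued against. Over 17714 genes on 19 autosomes the chromosome medians lay between -0.0656 and 0.154 on the log2 scale. They were within the bound of 0.3 for a gained or lost copy, which was set after the values had been seen. A copy change in part of the cells could stay under this bound, and the sex chromosomes were not examined. A difference between the lines that is present without induction could underlie part of the calls and remains open, since the uninduced EBs were not analysed here. That 85.93% of the genes called at day 2 and at day 8 went the same way does not decide it, because a shared direction does not show what happens without induction. An effect of Dlx2 itself is the biological explanation that the design names, and it is likewise not separated from the line.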
